A study of Petromyzon marinus with 6 samples.

How the data were processed

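RNA of TH+ and TH- cells from the trunk of sea lamprey larvae was measured by sequencing, in 3 libraries per group. Per the labels' protocols, tissue was dissociated and fixed in paraformaldehyde, cells were selected with an antibody, crosslinks were reversed, RNA was extracted with a NucleoSpin kit, and cDNA was made with a SMART-Seq ultra-low-input kit followed by NEBNext Ultra II libraries. The method, FRISCR (fixed and recovered intact single-cell RNA), was used here on sorted populations and not on single cells. Fixation and whole-transcript amplification of little RNA can shorten fragments and lose rare molecules, and no molecular identifiers were described, so counts are of reads and not of molecules.

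Each library came with 1 table of transcript models with the columns of kallisto, which the submitters' processing notes name together with DESeq2, with no version given for either. The transcript set, genome build and read filters are not given in the sources used here. The deposited estimated counts are kallisto's expected reads per model; they are not scaled for depth, and reads that fit several models are divided between them, so they need not be whole. The deposited TPM values are those counts divided by effective length and scaled to the same total in every library by the authors' kallisto run. The tables also give each model's length and its effective length in bases, which is the length reduced by an amount that depends on the library's fragment lengths. The 19781 models had a median length of 1398 bases, 62.3% of the lengths were multiples of 3, and 6 models were second transcripts of a gene. Models with whole counts in all 6 libraries (within 1e-06) held 48.5% of the TH+ counts and 35.2% of the TH- counts. The other models had a fractional count in at least 1 library, a sign of reads divided between similar models. How much of their counts was divided, and so uncertain between copies, is not known. There were 12 models that matched another in length and in all 6 values to 3 decimals.

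No genome was used. The model identifiers were looked up in a table of 45433 lamprey genes with symbols, from the assembly UKy_Petmar_22M1.pri1.0, and 0 matched. The files do not pair the identifiers with names, no coordinates are printed, and tests were made per model as deposited. The 25 gene lists and the naming rule that used symbols could not be applied, so the rule for files without symbols was used, which names 2 models in each direction. These lists covered catecholamine, sympathetic, neuronal, synaptic, channel, cholinergic, neuropeptide and neurotrophin receptor genes, markers of other trunk cell types, and cell cycle, stress, ribosomal and respiratory genes.

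Samples were grouped by their titles. Estimated counts were rounded to whole numbers. Models were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 11502 models, and libraries were scaled by TMM. The 2 groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05, with no covariate. Standard errors of fold changes were taken from the fold change and its F statistic. Fold changes against a group with no count were given as lower bounds from 3 counts over the pooled group. Totals, detected models, shares of counts and length differences (median over the 7146 models above 2000 bases) were compared with two-sided exact permutation tests in SciPy 1.17.1. CPM are counts relative to the library total, or where stated to the TMM-scaled total, and ratios between groups on library totals were taken from group mean CPM. The edgeR test was checked on simulated counts for this comparison with 200 changed models: of 10687 models tested, it recovered 72 of the 100 changed by 2-fold and 86 of the 100 changed by 4-fold, and 4.24% of its calls were false. In the data 75.8% of the tested models were called, so this does not check TMM scaling or false calls where most models differ. The ratio test was checked on simulated mixtures, where a profile with a share of 0.1 of another gave a lowest ratio of 0.0798 and an unmixed profile gave 0. The simulated profiles were drawn independently of each other. The check therefore does not show what lowest ratio unmixed cells with shared expression would give.

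The alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile scaling, no low-count filter and a stricter one, DESeq2 1.42.0 (with an adjusted p left as missing for 4199 models), limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), robust dispersion, effective-length offsets, thinning to the smallest total, a replicate block, a fold threshold of 1.5, and leaving out each library. Those added after the data were seen were library totals alone, models with whole counts only, a spread of its own per group (voomLmFit), removal of the 100 most abundant models, and offsets from a loess on length. The labels give no sequencing batch or date. Total depth was 6573171 to 9221265 counts per library.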

Results

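The series asked which transcripts mark the sympathetic neurons of the sea lamprey, Petromyzon marinus, a jawless vertebrate. Cells were taken from strips of tissue on both sides of the trunk of ammocetes, the larval stage, where the submitters presumed the sympathetic chains to lie. They were fixed, stained with an antibody against TH and sorted into TH+ and TH- cells. TH is tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis and a marker of noradrenergic neurons. RNA was recovered after the fixation was reversed and was sequenced in 3 TH+ and 3 TH- libraries. The labels do not say whether the 3 libraries of a group came from separate animals or sorts, so the p-values measure only the spread between these libraries, which may be technical.

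The tables listed 19781 transcript models under PMZ identifiers with no gene symbol. None of these identifiers was found in the lamprey gene table used here, so the TH transcript and the 25 gene lists fixed in advance, among them the markers of other trunk cell types, were not analysed here. The comparisons below are therefore between transcript models and between whole libraries.

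The libraries held between 6573171 and 9221265 estimated counts. The TH- libraries were on average deeper, with 8414153 ± 1126300 counts (SD, n = 3) against 6949160 ± 506500 (SD, n = 3) in TH+ libraries. The groups overlapped in depth. Replicates were close to each other, most of all in TH+. The chi-square statistic per degree of freedom between pairs of TH+ libraries was 3.27 to 3.90, and between pairs of TH- libraries it was 11.03 to 37.6. Each pair thus differed by more than counting noise, so no library was treated as a copy of another. This does not show that the libraries came from separate sorts or animals, since separately amplified parts of one sort would differ too. Pairs of a TH+ and a TH- library had values of 363.9 to 445.2. The coefficient of variation between replicates beyond counting error, from edgeR's common dispersion, was 9.24% in TH+ and 24.2% in TH-.

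The TH+ libraries contained a wider range of transcripts. At least 1 count was found for 16319 ± 21.6 models per TH+ library and 12976 ± 257 models per TH- library (SD, n = 3 each), a mean difference of 3343 models. The gap was present although the TH- libraries were deeper, and it was 3630.3 models after every library was thinned to 6573171 counts. With a minimum of 10 counts, 12243 ± 90.6 and 8123 ± 257 models were found. Of the models seen in all 3 TH+ libraries, 1237 had no count in any TH- library. Only 12 models showed the opposite pattern, and 10706 were seen in all 6 libraries. On library totals, the depth allowed a model with no count in the pooled TH- libraries a level of up to 0.119 CPM. In the pooled TH+ libraries it allowed up to 0.144 CPM, both from a limit of 3 counts. On the TMM scale, whose factors averaged 0.543 in TH- and 1.85 in TH+, the order reverses and the TH- limit is the higher. These limits and intervals cover counting error only.

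The TH- libraries were dominated by few transcripts. Their 100 most abundant models took 64.9% ± 1.95 of the counts, against 31.0% ± 0.276 for the 100 most abundant models of each TH+ library (SD, n = 3 each). In a TH- library 40.7 ± 3.06 models were enough to hold 50% of the counts, whereas a TH+ library needed 359.0 ± 5.29. The single most abundant TH- model, 976 bases long, took 6.37% ± 0.384 of TH- counts and 1.64% ± 0.118 of TH+ counts. The lists of the 100 most abundant models of the 2 groups shared 53 models. The sizes of the sequenced fragments also differed between the groups. The difference between a model's length and its effective length, which in kallisto output grows with the fragment length, was 139.8 ± 4.17 bases in TH+ and 102.6 ± 2.33 bases in TH- (SD, n = 3 each). For detection, the 100-model share and this length difference alike, the libraries of the 2 groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow.

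**Figure D1:**
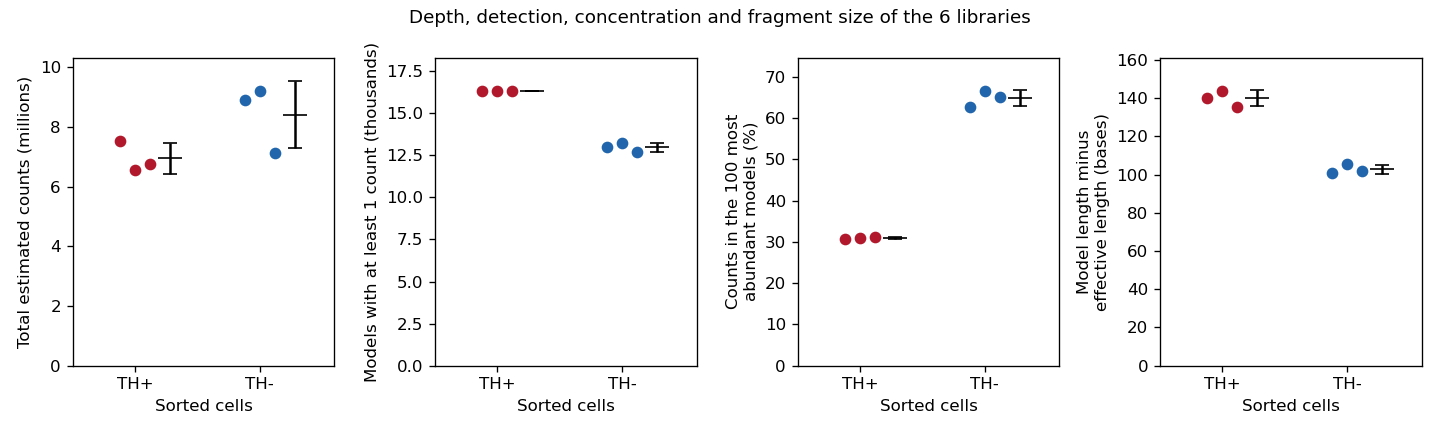
Each point is a library; the horizontal bars show the mean and the whiskers the SD of 3 TH+ (red) and 3 TH- (blue) libraries for total estimated counts, models with at least 1 count, percent of counts in the 100 most abundant models, and model length minus effective length in bases. TH- libraries were deeper on average yet held fewer models (12976 against 16319), more of their counts in 100 models (64.9% against 31.0%) and shorter fragments.

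TH+ and TH- cells differed in most of the transcript models that could be tested. Of 11502 models with enough counts, 4927 were higher in TH+ and 3789 were lower at an adjusted p of at most 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment, TMM scaling), which together made 75.8% of those tested. The 2786 other models did not pass the test. The libraries of the 2 groups did not overlap for 9095 of the 11502 models, or 79.1%, where chance gives 10%. Among the higher models 56.5% exceeded a 4-fold change and 9.23% a 16-fold change, and among the lower models 34.5% and 3.25% did so. Among the 865 models at 100 CPM or more in TH- on library totals, the lowest TH+ to TH- ratio was 0.0290 on the TMM scale of these fold changes. The median log2 fold change was 2.21 for higher models, with models absent from TH- set at their lower bound, and -1.58 for lower models.

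The direction of many smaller changes depended on how the libraries were scaled. The TMM factors averaged 1.85 in TH+ and 0.543 in TH-, which raised the effective TH+ depth relative to TH-. Under TMM the median log2 fold change of all tested models was 0.38 and 56.5% of the called models were higher. With upper-quartile scaling that share was 65.5%. With library totals alone it was 89.7%, with 8989 higher and 1028 lower models. With limma on log2(TPM + 1) it was 93.3%, with 9621 and 696. That setting also changed the test and divided counts by effective length, so its shift cannot be put down to scaling alone. Library totals moved fold changes by a median of 1.76 log2 units, and 1411 of the models called lower under TMM were then called higher. TMM takes most models as unchanged, whereas 75.8% of those tested were called. These data therefore do not settle which scaling is right, nor how many models were lower.

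The 5 scalings compared were TMM, DESeq2 size factors, upper quartile, library totals, and limma on log2(TPM + 1). The last also changed the test and divided counts by effective length, so it was not a change of scaling alone. Under all 5 scalings, 4921 models were higher and 696 were lower in TH+. Library totals alone in the edgeR test called 1028 lower. Relative to TMM the other scalings either left fold changes in place or moved them up, so this comparison could remove lower calls but hardly any higher ones, and the 696 are the lower calls of limma on log2(TPM + 1). The 4921 higher models took 34.9% ± 0.299 of the TH+ counts and 3.17% ± 0.108 of the TH- counts (SD, n = 3 each). The 696 lower models took 18.0% ± 0.654 of the TH+ counts and 68.0% ± 0.518 of the TH- counts. On library totals, the median log2 fold change of the first set was 3.96 and that of the second set was -1.48. Of the 100 models most abundant in TH-, 83 were among the 696 lower models and none among the 4921 higher models. As a group these 100 models fell from 64.7% ± 2.06 of the counts in TH- to 22.6% ± 0.407 in TH+. Of the 100 models most abundant in TH+, 27 were higher and 36 were lower under all 5 scalings. Those 100 models held 30.9% ± 0.293 of TH+ counts and 54.1% ± 2.30 of TH- counts.

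Models towards the ends of the distribution were named by a rule fixed in advance. It took the largest fitted log2 fold changes among separated, called models with a mean of at least 50 counts in the higher group. Where TH- had no count the fitted value is not fixed by the counts, so the 2 higher models need not be the largest changes. The largest fitted log2 fold change among tested models with TH- counts was 8.15. PMZ_0063747-RA, an 891-base model, had 572, 567 and 600 counts in the TH+ libraries and 0 in each TH- library, so that it was at least 207-fold higher in TH+ (edgeR adjusted p = 3.42e-08, limit of 3 counts over the pooled TH- libraries). Its level was 45.5 ± 3.49 CPM after TMM scaling (SD, n = 3), and its counts were not all whole, so part of its reads was shared with another model. PMZ_0051608-RA, of 1562 bases, had 140, 140 and 147 counts in TH+ and 0 in each TH- library, and was at least 50.9-fold higher (edgeR adjusted p = 2.66e-06). In the other direction, PMZ_0030947-RA, of 1485 bases, was at 0.390 ± 0.0583 TMM-scaled CPM in TH+ and 15.1 ± 3.42 in TH- (SD, n = 3 each), or 0.716 and 8.11 CPM on library totals, a log2 fold change of -5.22 with a standard error of 0.35 (edgeR adjusted p = 1.69e-07). PMZ_0050249-RA, of 6399 bases, was at 73.4 ± 5.84 TMM-scaled CPM in TH+ and 2534 ± 212 in TH- (134.95 and 1381.6 CPM on library totals), a log2 fold change of -5.11 with a standard error of 0.13 (edgeR adjusted p = 6.26e-10). On library totals these 2 models stood at 0.0883 and 0.0977 of their TH- level. These 4 models kept their direction and their call under the alternatives in which they were tested.

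Absence was one-sided. There were 230 models with no count in any TH- library and at least 10 counts in each TH+ library. The reverse held for 1 model, PMZ_0060270-RA, which was chosen after its values were seen. It had 17, 29 and 15 counts in the TH- libraries, and its counts were not all whole, so part of its reads was shared with another model. Among the 865 models at 100 CPM or more in TH- on library totals, the TH+ to TH- ratio was never below 0.0977. Among the 1772 models at 100 CPM or more in TH+, the reverse ratio was below 0.05 for 183 models, or 10.3%, and its lowest value was 0.00108. On TMM-scaled CPM the same sets gave a lowest ratio of 0.0290, with 48 of the 865 models, or 5.55%, below 0.05, and a lowest reverse ratio of 0.00367, with 42 of the 1772 models, or 2.37%, below 0.05. The share of models below 0.05 was thus larger in one direction on library totals and in the other on the TMM scale.

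**Figure D2:**
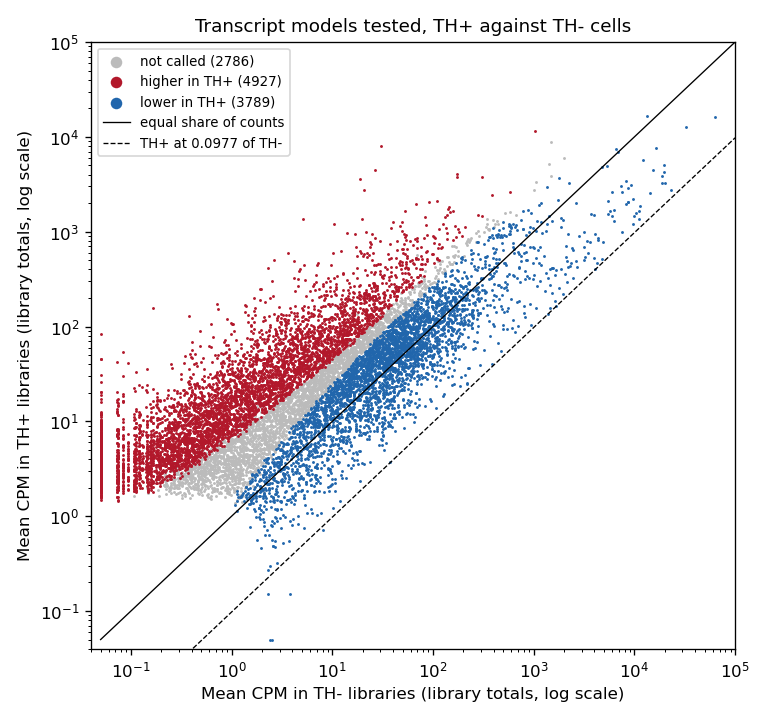
Each point is a tested transcript model, with its mean CPM on library totals in 3 TH- libraries (x axis) and 3 TH+ libraries (y axis), both on log scales, with values under 0.05 drawn at 0.05; colours give the edgeR call under TMM scaling (4927 higher, 3789 lower, 2786 not called), which is why blue points lie on both sides of the solid line of equal CPM. The dashed line marks a TH+ level of 0.0977 of the TH- level, below which no model at 100 CPM or more in TH- fell.

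By mean TMM-scaled CPM over the 6 libraries, the share of higher calls went down at each step from the least to the most abundant quintile, and that of lower calls went up. In the least abundant quintile 64.2% of the models were higher and 2.91% lower in TH+, and in the most abundant 21.0% were higher and 68.5% lower. The filter fixed part of this, since of the 2301 models in the least abundant quintile 2206 reached its minimum in all TH+ libraries and 16 in all TH- libraries. The ranking can shape it too, because a mean over both groups contains the change itself. Calls also differed by the length of the models. In the shortest quintile, of 132 to 1004 bases, 52.6% of the models were higher and 23.3% lower. In the longest quintile, above 3825 bases, 36.3% were higher and 41.1% lower. Fragment length differed between the groups in all libraries, as given above. The share of higher calls was 16.3 percentage points larger in the shortest than in the longest quintile. Within quintiles of abundance this difference ranged from 9.36 points in the least abundant, which held 935 of the shortest models, to -5.00 points in the most abundant.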

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

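The tests of depth, of dominance by a few models, of lost molecules, of fragment length and of abundance were set before their results were seen, as was the test of the ratio at 10 to 30 CPM. The tests of two-way exchange and of low counts at the lowest ratio, and the binomial tests against that ratio, were chosen after the pattern was seen.

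Effective lengths, which the main edgeR test did not use, differed between the groups. The difference between length and effective length was 37.1 bases larger in TH+ than in TH- libraries, so TH- fragments were shorter in every library.

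The TH+ to TH- ratio on library totals had a lower edge. Among models at 100 CPM or more in TH- it never fell below 0.0977 (in TPM, 0.123 among the 441 models at 100 TPM or more). The 17 models within 1.3 times 0.0977 had a median of 3455 TH+ counts over the 3 libraries, enough to measure such a ratio. Counts of that size follow from the limit of 100 CPM and the ratio itself, so they are not separate evidence on the edge. A two-way exchange of reads between libraries is argued against by the reverse ratio, whose 1st percentile was 0.0083. A candidate explanation is that a share of the TH+ reads came from RNA of the TH- kind, such as carried-over cells or free RNA. The lowest ratio, 0.0882 to 0.103 in single TH+ libraries, could at most bound that share from above. Expression by TH+ cells themselves adds to the ratio, so it does not give the size of the share. Of 1942 models at 10 to 30 CPM in TH-, 0 lay below 0.0488. The 3493 models at 10 to 100 CPM did not set the edge. By an exact one-sided binomial test 0 of them lay below 0.0977, adjusted or at an unadjusted p under 0.05. In the reverse direction 1009 of 5574 did (Benjamini-Hochberg adjusted). Most of the 3493 models lay far above the edge, with a median ratio of 2.45 and a 1st percentile of 0.241 at 10 to 30 CPM. The counts of 0 therefore do not by themselves tell mixing from its absence. The binomial test covers counting error only and leaves out the spread between libraries. The contrast between directions holds on library totals, the scale on which reads would be mixed. On TMM-scaled CPM the lowest ratios were 0.0290 and, in reverse, 0.00367, with 1st percentiles of 0.0334 and 0.0284. Low expression of the same transcripts by TH+ cells themselves remains open and was not tested; under the first reading the folds of lower models would be understated and those of higher models little changed.

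Fewer models were detected in TH-, by 3343 per library. The TH- libraries were deeper on average, which itself argues against depth. Thinning to equal depth took more counts from TH- on average, so a lasting gap, of 3630.3, could be foreseen and is not separate evidence. Without the models among the 100 most abundant of either group, and with the other 19634 models thinned to 2341052 counts per library, the gap was 2878.0, which argues against dominance by a few models as the whole cause. Loss of molecules in small samples cannot be told apart from a narrower transcriptome in TH- cells: 0.175% of the TH- models expected at 10 or more counts were at 0, against 0.104% in TH+, a value between the bounds set in advance, and a loss before a sample was divided would be shared by its libraries. The biological difference between the sorted cells stays open. RNA of the TH- kind in the TH+ libraries, the candidate given above for the lower edge, would also add detected models to TH+. Its part in the gap and in the one-sided absence of counts was not tested.

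Short models were more often higher in TH+ than long ones, by 16.3 percentage points between the outer quintiles of length. Offsets from the effective lengths left a difference of 18.5 points. Lengths were reduced by more bases in TH+, so these offsets act to raise short models in TH+. They could not have removed the difference, so this outcome followed from the fragment lengths and is not separate evidence. Acting through effective length, the shorter TH- fragments would work against the pattern. The rule set in advance for abundance as the cause compared only the mean difference within quintiles of abundance with the pooled one. At -0.265 points, against 16.3 pooled, it was met. The mean hides differences that went both ways, from 9.36 in the least abundant quintile to -5.00 in the most abundant. The filter on library totals also admits models of low TMM-scaled CPM mainly through TH+. For these reasons, which were not part of that rule, whether the abundance of short models accounts for the pooled difference stays open. A bias of fragment length that acts in another way was not tested.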

How the results depend on the processing

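Across 23 alternatives, 19 left the number of higher models, and 19 the number of lower models, within 1.5 times the values of 4927 and 3789. The exceptions were limma on log2(TPM + 1) with 9621 higher and 696 lower, limma on log2(TPM + 0.1) with 9541 and 672, library totals alone with 8989 and 1028, and models with whole counts only with 3250 and 2311. The last tested only 7088 models. The first 3 scale each library to its total, in counts or TPM, without the further factor that TMM applies. They called higher 1944, 1879 and 1411 of the models that were lower under TMM. The limma settings among them also changed the test and divided counts by effective length. DESeq2 gave 5034 and 3835. The replicate block gave 4530 and 3618. Same-numbered libraries had correlations of 0.00927, 0.0242 and 0.00045 between their deviations. These values gave no reason to pair them, but they cannot show whether such libraries shared an animal or a sort. Leaving out 1 library gave 4578 to 5317 higher and 3563 to 3928 lower models. The 4 models named by the fixed rule kept their direction and call, with adjusted p of at most 0.000101. The gap in detected models was 4119.7 with a minimum of 10 counts, 3630.3 after thinning, and 3212.7 to 3469.7 without 1 library. The share of each library's own 100 most abundant models was larger in TH- by 33.9 points in counts and 29.5 in TPM. Tests of genes instead of models and of the gene lists were not run, for lack of gene names. The 3 and 3 libraries make 10 splits, too few for a share under 0.05. The real split called 8716 models and the highest other split 0 (edgeR), with at most 19 models at an unadjusted p under 0.05 in any other split. Every other split mixes TH+ and TH- libraries in both groups, which widens the spread within them. Few calls were therefore assured there, and the contrast does not measure false calls. In the simulation, where only 200 models changed, 28 of 100 changes of 2-fold were missed at this depth.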

Other observations

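Models with consecutive identifier numbers moved together more than chance gives, in a test set before its result was seen. Over 6475 pairs of tested models numbered 1 apart, log2 fold changes correlated at r = 0.141 across models, which are not independent replicates, and the highest of 1000 shuffles was 0.0464. Among the 2600 pairs of models with whole counts, which show no sign of divided reads, r was 0.130 and the highest shuffle 0.065. Whole counts do not prove that no reads were shared. A candidate explanation is that neighbouring numbers mark neighbouring or duplicated genes with related expression, which needs the positions of the models to test further.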
